A study of Mus musculus with 2 samples.

How the data were processed

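ATAC-seq peak lists from 1 wild-type and 1 Dnmt3a knockout culture of mouse bone marrow-derived mast cells were analysed. Per the labels' protocols, marrow of mice aged 3 to 4 weeks was cultured for 4 weeks in interleukin 3, over 95% of cells carried Kit and the IgE receptor, nuclei were prepared with 0.1% Igepal and treated with a home-made Tn5, and libraries were sequenced as 50 bp single reads to a stated depth of 10 M reads. Per the submitters' processing notes, Trimmomatic, Bowtie2 and MACS2 were used with mm10 and GRCm38; their versions, parameters and any shift of reads to the Tn5 cut site are not given in the sources used here. A shift of a few bases would move peak edges slightly.

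Per the file layout, the authors deposited 1 list of called peaks per sample, with a score, a fold enrichment and the −log10 of a p-value and of a q-value per peak. The deposited score was 10 times the −log10 q-value in 100% of peaks. The authors' fold was read as the ratio of summit pileup to local background, each with a pseudocount of 1, and their p as a Poisson p. These values were used to describe and rank peaks within their own list, and as common limits on −log10 q in counts of peaks and regions. A common limit is not equally strict in both lists if depth or enrichment differed. The deposited fold and −log10 p together gave a whole-number summit pileup and a local background for 100% of peaks (tolerance 0.001 in −log10 p), used to judge depth and enrichment. The lowest local background was 0.0644 in the wild-type and 0.0599 in the knockout library. Median peak width was 150 and 154 bp, and the covered length 3.00 and 3.49 Mb.

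Peaks that shared an interval were merged and the lists compared with bedtools 2.31.1, at least 1 bp of overlap counting as shared. Analyses used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1. Genes came from a table of assembly GRCm38.p6, the build mm10 names, with 21631 protein-coding genes. It gives gene intervals without strand or exons, and no genome sequence was used here. The promoter classes planned before the data were examined were therefore replaced by the distance to either gene end (1 kb), and the nearest transcription start by the nearest gene interval within 100 kb. Planned results on CpG content and sequence motifs are not reported, and exons and introns are not resolved.

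With 1 library per genotype there was no test between genotypes. Shares have exact (Clopper-Pearson) binomial 95% intervals that cover counting error only. Gene lists are placed among 10000 random lists matched on regions per gene, which describes these 2 libraries. Of 370 listed genes 368 were used. Tpsab1, a pseudogene in this table, and Ahsp were not. Vamp7 and Hbb-b1 were placed by the table at the very start of chromosomes X and 7 (from bases 10737 and 38285). Their lack of any region may reflect that placement. The rule for the genes named was fixed before the data were examined, and parts of it pick genes by their values: the 10 strongest regions of each unshared class, Dnmt3a, 10 mast cell genes and up to 3 members per list with the largest difference of knockout-only and wild-type-only regions, ties going to the gene with more regions. Meis2, Fli1, Syk, Vav1, Ccl9 and Stat3 were added after their values were seen, as members that differed in the other direction. Some list members that this rule names are not reported here. The steps were tested on simulated data: 100% of 1456 simulated pileups and all placed shared and unshared regions were recovered, and 6.5% of 200 unchanged lists fell outside the 2.5 to 97.5 percentiles. Simulated sites lay far apart and simulated pileups followed the assumed formula. Their full recovery therefore checks the code only, and not the handling of closely spaced regions.

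Alternatives were a −log10 q of at least 5 in both lists or on one side, equal numbers of peaks, a reciprocal overlap of 50%, summits within 200 bp, no chromosome X, gene ends of 2.5 kb or of all gene types, and gene bodies with 10 kb. Leaving out chromosome 19 and assignment by the nearest gene boundary were added after the data were seen.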

Results

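Open chromatin was mapped by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into accessible DNA, in mouse bone marrow-derived mast cells. These are mast cells, the IgE-binding granulocytes of tissues, grown from bone marrow in interleukin 3. The data comprised 1 wild-type library and 1 library from mice lacking Dnmt3a, a de novo DNA methyltransferase. The question was how loss of Dnmt3a relates to chromatin accessibility in these cells. Peaks had been called in each library separately, giving 17170 wild-type and 19684 knockout peaks on chromosomes 1 to 19 and X. The lists carry no total read count. The peak summits give the depth behind each call, with a median pileup of 9 overlapping fragments in both libraries. There was no replicate of either genotype, so no difference below has been set against a spread between animals, and the intervals (exact binomial, 95%) cover counting error only. All coordinates are 1-based on mm10.

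At the Dnmt3a gene itself (chromosome 12, 3801559 to 3914443), the wild-type list held 6 peaks and the knockout list 5, and 4 regions were shared. The wild-type list had a peak at 3897094 to 3897359, inside the gene and 17.1 kb from its upper end, with a fold enrichment of 13.9, a −log10 q of 21.8 and a summit pileup of 21 in the authors' list. The knockout list held no peak there. By −log10 q it ranked first among all 3952 wild-type-only regions. The wild-type list also had a peak of its own at 3868718 to 3868880, and the knockout list one at 3823626 to 3823725. Beyond the last shared region, which ended at 3871300, the remaining 43.1 kb of the gene held 1 wild-type peak and 0 knockout peaks. This locus gives a check of the genotype labels only as far as the engineered allele touches that stretch, which the labels do not state.

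**Figure D1:**
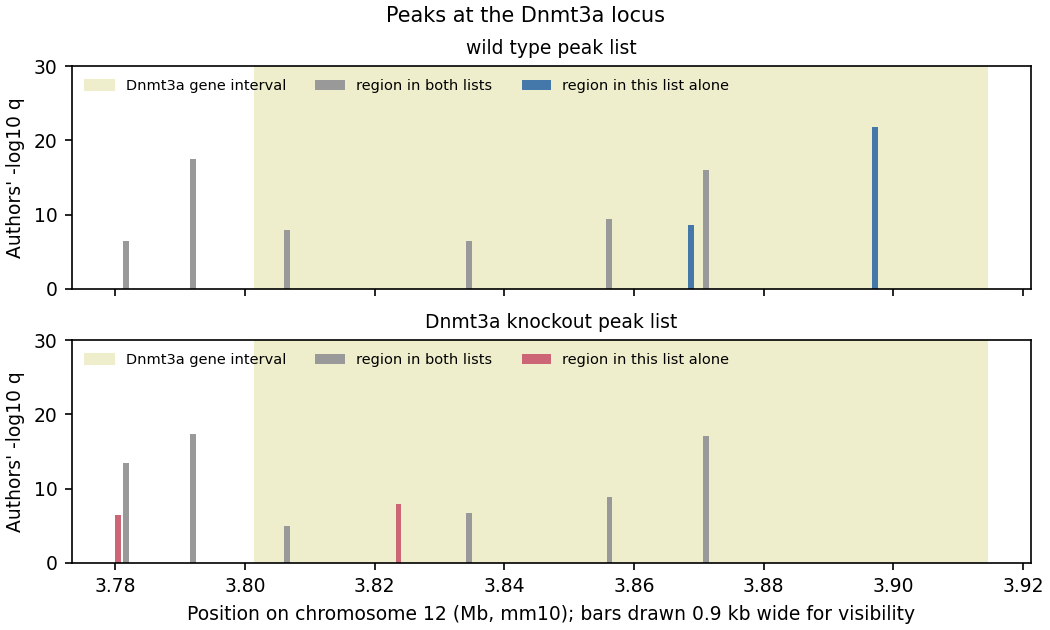
Peaks at the Dnmt3a locus in the wild-type list (top) and the knockout list (bottom), with position on chromosome 12 in Mb on the x axis and the authors' −log10 q on the y axis. Grey bars are regions found in both lists and coloured bars regions found in that list alone; the wild-type bar near the right end of the gene is the peak at 3897094 to 3897359.

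The 2 accessibility maps shared most of their strong sites. Of the wild-type peaks, 77.0% (13218 of 17170; interval 76.3 to 77.6) were overlapped by a knockout peak by at least 1 bp. Of the knockout peaks, 66.8% (13143 of 19684; interval 66.1 to 67.4) were overlapped by a wild-type peak. Random placement on the same chromosomes gave mean overlaps of 0.293% and 0.253% over 100 placements. Overlap followed peak strength within each list: it was 48.6% in the weakest of 10 equal classes of wild-type peaks and 99.9% in the strongest, and 30.5% and 99.8% in the corresponding classes of knockout peaks. Peaks without a partner had a median summit pileup of 6 in both lists, against 10 for wild-type and 11 for knockout peaks with one.

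**Figure D2:**
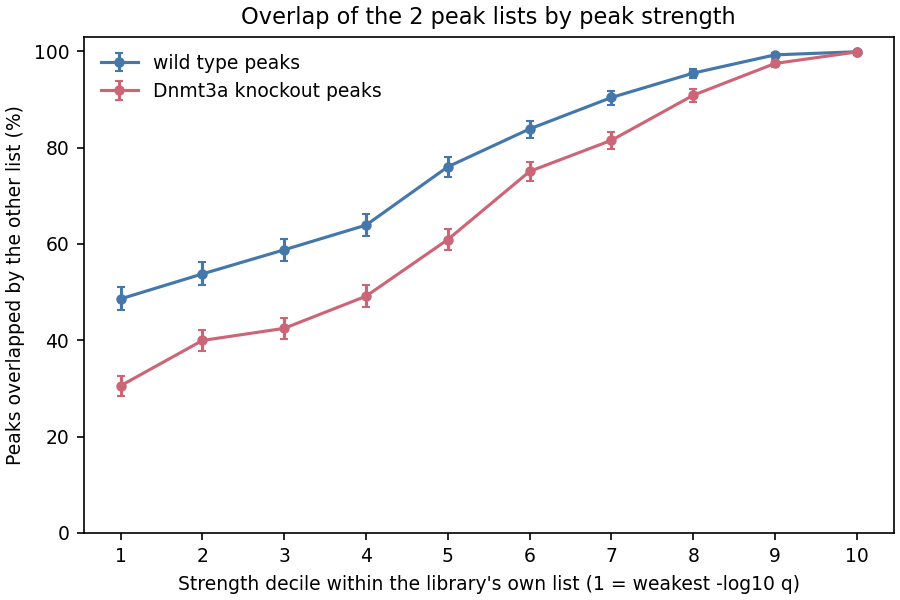
Percent of peaks overlapped by the other list (y axis) in 10 strength classes of each list by the authors' −log10 q (x axis, weakest to strongest), with exact binomial 95% intervals. Both curves reach 99.8% or more in the strongest class, and the knockout curve starts lower, at 30.5%.

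More regions were found in the knockout library alone than in the wild-type library alone. The merged lists gave 23364 regions, of which 12871 (55.1%) were shared, 6541 (28.0%) were knockout-only and 3952 (16.9%) were wild-type-only. The ratio of knockout-only to wild-type-only regions was 1.66 (interval 1.59 to 1.72), and the ratio of all peaks was 1.15 (1.12 to 1.17). When the knockout list was reduced to its strongest 17170 peaks, the ratio of regions was 1.03, which follows largely from giving both lists the same length. Among stronger unshared regions it was higher, at 2.99 (700 against 234) for a −log10 q of at least 10 in the list that held the region, 8.22 (74 against 9) for at least 15 and 6 (6 against 1) for at least 20. The whole knockout list also held more peaks past these limits, 8329 against 6695 at 10, 4239 against 3103 at 15 and 2167 against 1402 at 20. Knockout-only regions outnumbered wild-type-only regions on 20 of 20 chromosomes, with ratios from 1.38 on chromosome 15 to 2.36 on chromosome 19. Among summits of the unshared peaks, 18.8% of wild-type and 12.05% of knockout summits lay within 1 kb of a summit of the other list.

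**Figure D3:**
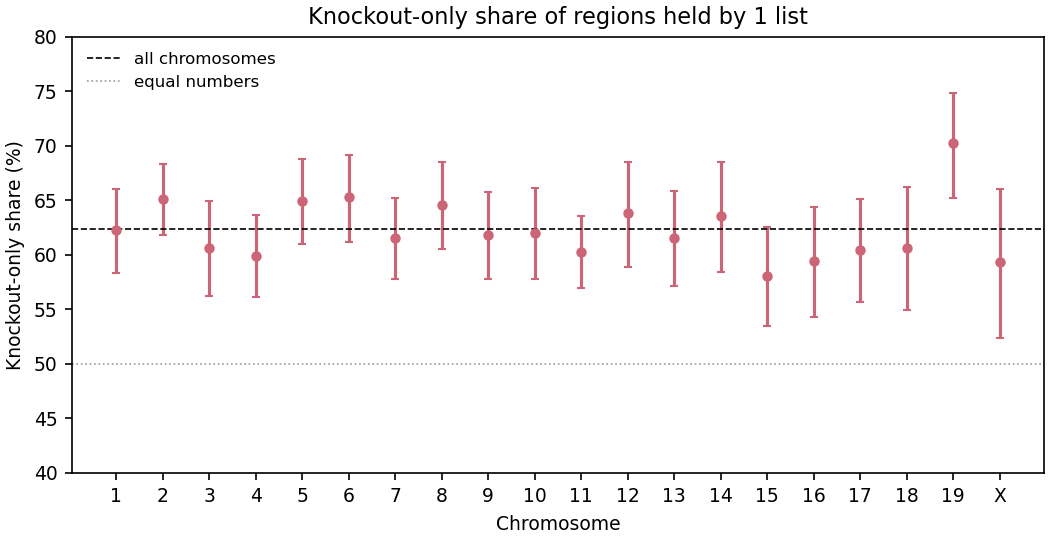
Knockout-only regions as a percent of the regions held by 1 list (y axis) on each chromosome (x axis), with exact binomial 95% intervals; the dashed line is the value over all chromosomes, 62.3%, and the dotted line marks equal numbers. Chromosome 19 has the highest share, 70.2%.

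The strongest knockout-only regions lay at Rlf, a zinc finger gene (chromosome 4, 121215085 to 121215245, −log10 q 25.1), 40.5 kb from Vav3, a guanine nucleotide exchange factor gene (chromosome 3, 109299789 to 109300014, 22.9), and at Rab8b, a vesicle transport gene (chromosome 9, 66919674 to 66919889, 21.0). Next came regions 209 kb from Tle3, inside Hdac7, which encodes a histone deacetylase, 96.3 kb from Hs3st3a1, inside Ralgps1, over Necab3 and 1700003F12Rik, 28.8 kb from Inpp5a and 1144 kb from Efnb2. After the Dnmt3a region, the strongest wild-type-only regions lay 34.1 kb from Lrrc32 (chromosome 7, 98535921 to 98536116, −log10 q 19.9), at an end of Dennd1c (chromosome 17, 57078448 to 57078607, 18.3) and inside Nol4l (chromosome 2, 153493964 to 153494150, 17.3). The others lay 740 kb from Nap1l3, inside Tspan31, at Klhl11, 40.8 kb from Bcar3, inside Inpp4b, which encodes a phosphoinositide phosphatase, and inside Ccdc91. These −log10 q values rank peaks within their own list.

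Regions found in 1 library lay away from gene ends more often than shared regions. Within 1 kb of either end of a protein-coding gene were 43.8% of shared (interval 43.0 to 44.7), 27.5% of wild-type-only (26.1 to 28.9) and 24.7% of knockout-only regions (23.7 to 25.8), against 3.48% of randomly placed knockout peaks. Inside genes but farther from their ends were 33.5%, 41.6% and 45.0%, and between genes 22.7%, 30.9% and 30.3%. Part of this goes with strength, since shared peaks matched to the unshared ones on −log10 q were near gene ends in 36.8% (wild type) and 35.6% (knockout).

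Of 21 mast cell effector genes, 12 had a region in the wild-type list and 16 in the knockout list, and of 19 mast cell transcription factor genes 19 and 18. These counts were not set against those of all genes, and the knockout list was the longer (19684 against 17170 peaks). Regions were assigned to the nearest protein-coding gene within 100 kb, so that a region of a gene need not touch it. Kit, the stem cell factor receptor gene, had 4 shared regions and 1 knockout-only region, Gata2 had 2 and 1, and Mitf, a mast cell transcription factor gene, had 5 shared, 4 wild-type-only and 4 knockout-only regions. Ms4a2, the IgE receptor beta chain gene, and Tpsb2, a tryptase gene, each had 1 shared region and no other. Fcer1a, the receptor alpha chain gene, had 1 shared region and a wild-type-only region over its upper end (chromosome 1, 173227141 to 173227296). Cpa3, the carboxypeptidase gene of mast cell granules, had 1 shared, 2 wild-type-only and 1 knockout-only region. Among cytokine genes, Tnf had 1 shared region, Il6 had 3 shared and 2 knockout-only, and Il13 had 2 regions, both knockout-only. One of these overlapped the upper end of Il13 (chromosome 11, 53634642 to 53634769, −log10 q 7.58), and the nearer knockout-only region of Il6 (chromosome 5, 30012888 to 30013018) lay beside a shared region at 30013181 to 30013347.

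Of the 19 fixed gene lists, 0 lay outside the central 95% of 10000 random lists matched on regions per gene. For 5 of them (neutrophil, B cell, T and NK cell, neuron and liver genes) that range ran from 0 to 100%, so that no value could lie outside it, and for 4 more (germline, basophil, macrophage, and erythroid and megakaryocyte genes) it reached 100%. Over all unshared regions, 62.3% were knockout-only. Mast cell effector genes had 10 knockout-only and 8 wild-type-only regions (55.6%, percentile 25.5). Their balance turned to 6 against 10 with equal numbers of peaks and to 7 against 8 without chromosome 19. Slc18a2, the vesicular monoamine transporter gene, had 3 knockout-only regions, 2 of them overlapping the gene, and Il1rl1, the interleukin 33 receptor gene, 3 shared and 2 wild-type-only. Mast cell transcription factors had 27 and 18 (60%, percentile 32.1), with 5 knockout-only regions assigned to Erg (4 overlapping the gene), 4 to Ikzf2 (1 overlapping) and 3 to Ikzf1 (3 overlapping), and 0 wild-type-only regions assigned to any of these. Meis2 (0 against 2) and Fli1 (2 against 4) had more wild-type-only regions. IgE receptor and Kit signalling genes had 28 and 13 (68.3%, percentile 76.7), including 4 knockout-only regions assigned to the kinase gene Lyn (2 overlapping it), 4 against 1 inside Prkcb and 2 against 0 for the phosphatase gene Inpp5d (1 overlapping it). Differences as large as that of Inpp5d in the other direction, 0 against 2, were found for the kinase gene Syk and for Vav1.

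Cytokines and chemokines had 20 knockout-only and 10 wild-type-only regions (66.7%, percentile 66.0), with 2 knockout-only regions each near Osm and Tgfb1, none of them overlapping the gene, and 2 wild-type-only and 0 knockout-only regions assigned to Ccl9. The 2 Tgfb1 regions lay side by side (chromosome 7, 25705780 to 25705879 and 25705894 to 25706019) and may be 1 site. Inflammatory transcription factors had 28 and 17 (62.2%, percentile 45.6), with 3 against 0 assigned to Cebpb and 3 against 1 to both Egr1 and Nfkbiz, and 0 against 2 to Stat3. None of the Cebpb and Egr1 regions overlapped the gene, and 2 of the 3 knockout-only regions of Cebpb and 2 of the 3 of Nfkbiz lay over 10 kb away. These 2 Nfkbiz regions also lay side by side. The Egr1 regions were nearer, the knockout-only ones 252, 1152 and 6500 bp and the wild-type-only one 242 bp from the gene. Eicosanoid and granule release genes had 16 and 6 (72.7%, percentile 83.7), with 3 knockout-only regions assigned to Stxbp2 (2 overlapping it) and 2 to Stx11 (both over 10 kb away). DNA methylation genes had 6 and 5 (54.5%, percentile 26.4), with 2 knockout-only regions assigned to Tet2 (1 overlapping it) and 2 against 1 to Gadd45g (0 overlapping). The knockout-only regions of Gadd45g lay 44 and 6780 bp from it, and the wild-type-only region 60089 bp. Germline genes that methylation keeps silent had 4 and 2 (66.7%, percentile 54.9), with 3 knockout-only regions assigned to Dazl (0 overlapping it and 2 over 10 kb away), 1 inside Ddx4 and 1 wild-type-only region inside Piwil2. The Piwil2 region (chromosome 14, 70395296 to 70395395) lay beside a shared region that ended at 70395286. Counted over gene bodies with 10 kb on each side, the germline list had 2 knockout-only and 3 wild-type-only regions. Of 22 germline genes, 5 had a region in the wild-type list and 5 in the knockout list. Methylation was not measured in these libraries.

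Cell cycle genes had the highest share among lists with at least 5 unshared regions, 16 against 4 (80%, interval 56.3 to 94.3, percentile 94.2). With a −log10 q of at least 5 in both lists they lay outside the central range (percentile 99.2), as they did with equal numbers of peaks (99.1) and the limit on one side (98.8), while assignment by gene bodies with 10 kb gave 89.7 and by the nearest gene boundary 90.5. These settings largely reuse the same regions and are not independent. With 19 lists, of which 14 could leave their range, 1 list outside it may arise by chance. Of 4 knockout-only regions assigned to Myc, which had no other, 1 overlapped the gene and 3 lay over 10 kb away. Ccnd3 held 2, and Ccnd2 was assigned 2, with 1 overlapping it. Stem and progenitor genes had 12 and 11 (52.2%, percentile 12.9), with 3 against 2 assigned to Mecom, 2 against 1 to Angpt1 and 1 against 2 to Cd34. Housekeeping genes had 6 and 8 (42.9%, percentile 5.49), with 2 wild-type-only regions assigned to Ppia, and 1 wild-type-only and 2 knockout-only to Actb. The wild-type-only region of Actb (chromosome 5, 142932469 to 142932572) lay beside 1 of the knockout-only regions (142932261 to 142932425). Over gene bodies with 10 kb the housekeeping balance turned to 9 against 7 (percentile 31.4).

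Among markers of other blood cells, 6 of 18 neutrophil genes had a region in the wild-type list and 7 in the knockout list. The numbers were 7 and 6 of 20 macrophage, 5 and 5 of 14 B cell and 6 and 7 of 17 T and NK cell genes. They were 8 and 8 of 18 erythroid and megakaryocyte genes. The short basophil list held regions at most of its genes, 4 and 3 of 5. Shared regions numbered 9 for basophil, 6 for neutrophil, 8 for macrophage, 7 for B cell, 7 for T and NK cell and 8 for erythroid and megakaryocyte genes. Over all regions, 55.1% were shared. Knockout-only and wild-type-only regions numbered 3 and 2 for basophil genes (percentile 41.9), 3 and 2 for neutrophil genes (46.2), 3 and 3 for macrophage genes (27.1), 1 and 1 for B cell genes (28.9), 4 and 0 for T and NK cell genes (93.3) and 6 and 2 for erythroid and megakaryocyte genes (75.0). Of 18 neuron genes, 3 had a region in the wild-type list and 2 in the knockout list, and of 17 liver genes 2 and 3, against 17 and 16 of 18 housekeeping genes. Knockout-only and wild-type-only regions numbered 1 and 1 for neuron genes (percentile 37.1) and 2 and 1 for liver genes (51.1). Among basophil genes, Itga2 had 3 knockout-only and 1 wild-type-only region and Prss34 a wild-type-only one. Knockout-only regions overlapped Pax5 (1), Itga2b (2), Vwf (1), Gp9 (1) and Tat (1). Of 3 assigned to Tcf7, 1 overlapped it and the other 2 lay side by side (chromosome 11, 52318445 to 52318544 and 52318612 to 52318711). Those assigned to Cebpe (1), Marco (2), Eomes (1) and Gad2 (1) did not overlap the gene, and the Eomes region lay 86175 bp away. A wild-type-only region overlapped Csf3r, and 1 each was assigned to Ctsg, Fcgr1, Adgre1, Igll1 and Neurod1 without overlapping it.

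**Figure D4:**
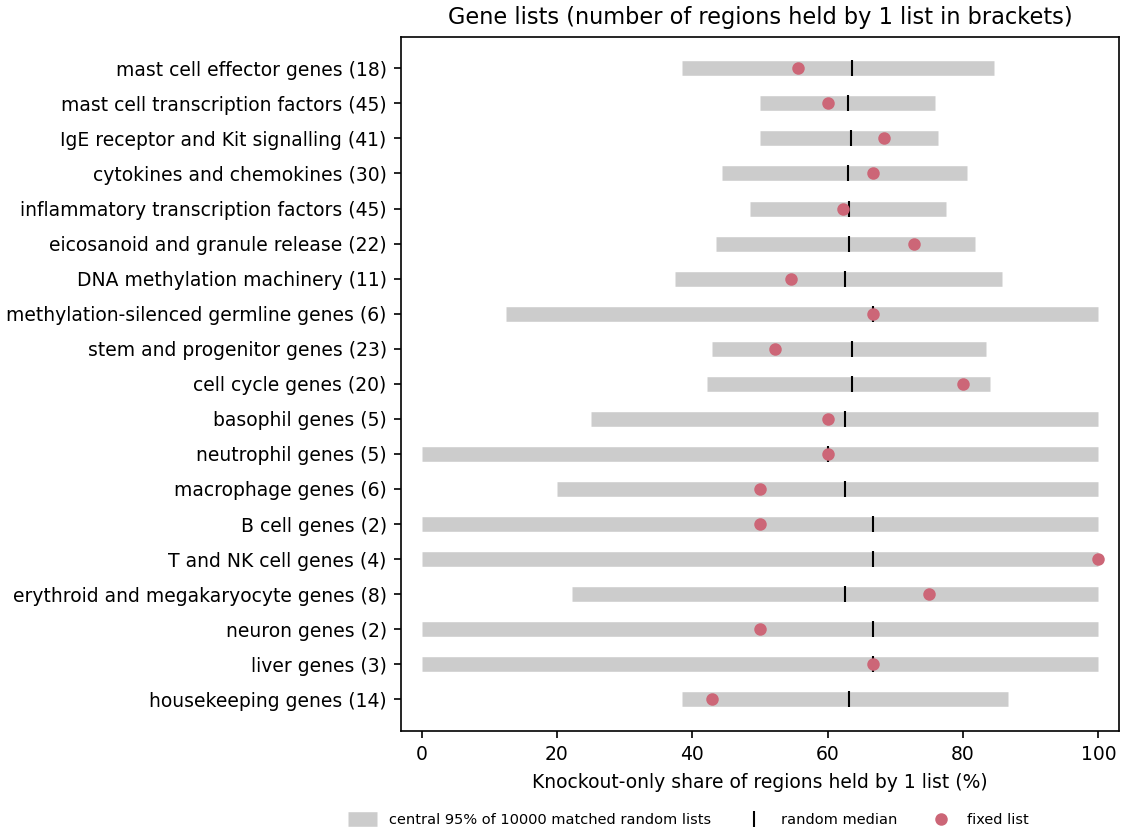
Knockout-only share of the regions held by 1 list (x axis, percent) for each of 19 gene lists (y axis, number of such regions in brackets). Grey bars span the central 95% of 10000 matched random lists, ticks mark their median and red points are the fixed lists; no point lies outside its bar.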

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

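No paired analysis was possible because each genotype had 1 library. Leaving out chromosome X moved none of the overlap, ratio and gene-end values beyond its interval; leaving out chromosome 19 (chosen after the data were seen) was run for the ratio of unshared regions and the gene-end shares, and moved none of these. The cause of the shifts below was not tested, except where the setting sets it. Wild-type peaks overlapped were 77.8% with a −log10 q of at least 5 in both lists, 72.7% with equal numbers of peaks, 80.3% with that limit on one side, 66.9% with a reciprocal overlap of 50% and 77.6% by summits within 200 bp. Knockout peaks overlapped were 71.9% with equal numbers, 70.4% with the one-sided limit and 58.4% with the reciprocal overlap. The ratio of knockout-only to wild-type-only regions was 1.76 with the limit in both lists, 1.03 with equal numbers, which fix the list lengths, 1.75 with the one-sided limit and 1.44 with the reciprocal overlap. Raising the one-sided limit moved it further, to 2.99 (700 against 234) at 10, 8.22 (74 against 9) at 15 and 6 (6 against 1) at 20. Knockout-only regions at gene ends were 25.8% with the limit in both lists, 31.2% within 2.5 kb and 30.3% for all gene types, and wild-type-only regions 34.2% within 2.5 kb and 32.9% for all gene types. The number of gene lists outside the central 95% of random lists was 0, and 1 with the limit in both lists, 1 with equal numbers and 1 with the one-sided limit; each time it was cell cycle genes (percentiles 99.2, 99.1 and 98.8). The balance of knockout-only to wild-type-only regions turned in 5 lists: mast cell effector genes (6 against 10 with equal numbers, 7 against 8 without chromosome 19), DNA methylation genes (4 against 6 with equal numbers), stem and progenitor genes (9 against 10 with the limit in both lists, 9 against 12 with equal numbers), and, over gene bodies with 10 kb, germline genes (2 against 3) and housekeeping genes (9 against 7). Basophil genes went from 3 against 2 to 3 against 0 with the one-sided limit, liver genes from 2 against 1 to 2 against 0 over gene bodies with 10 kb, and macrophage genes from 3 against 3 to 1 against 4 with equal numbers. Alternatives for CpG content and motifs were not run, as no genome sequence was used, and those for transcription starts were run on gene ends. Median pileups of 6 at unshared summits limit what absence from a list can show.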

Other observations

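Tests chosen only after the result was seen were those of sequencing depth, the second version of the enrichment test, the genotype as a cause, swapped labels, counting noise, DNA removal and an extra chromosome copy; the genes singled out here were also chosen after their values were seen.

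At least 5 more knockout-only than wild-type-only regions were assigned to 25 genes, against a mean of 17.0 (range 5 to 33) when the genotype was reassigned at random among unshared regions, and 2.4% of 1000 reassignments gave as many. The reassignment treated unshared regions as independent. Some of the same class lay side by side, such as 2 knockout-only regions assigned to Nfkbiz (chromosome 16, 55754426 to 55754535 and 55754580 to 55754679). The 2.4% may therefore be too low and does not exclude random scatter. Zmiz1 had 11 against 2, Prkca, which encodes a protein kinase C, 7 against 1, Creb5 6 against 0, Snd1 6 against 0 and Arsb 7 against 1. At least 4 more wild-type-only regions were assigned to 6 genes, among them Pde4b with 5 against 1, against a random mean of 6.50. Bunching of knockout-only regions in windows of 1 Mb was as large in 8.7% of reassignments, so random scatter was not excluded there either. In each list, 4 peaks over or beside the ribosomal RNA gene Rn18s-rs5 on chromosome 17 had local backgrounds of 35.3 or more.

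The knockout library had more regions of its own. Deeper sequencing as the whole cause was argued against by its background level, 0.93 times that of the wild type, on the assumption that both lists were made with the same fragment extension. At the 12871 shared regions the summit pileup in the knockout library was 1.09 times that in the wild-type library. At strong shared regions this ratio was 1.12 within 1 kb of gene ends and 1.08 away from them. Higher pileups at shared sites over a lower background would follow from stronger enrichment in the knockout library. Such enrichment throughout that library stays open after 3 versions of its test. The first, thinning knockout pileups by the ratio at shared regions, left 1.14 times the wild-type number but moved almost no peak past the calling limit; the second, written after that value was seen, gave 1.003 at pileups of at least 10, 1.049 at 20 and 1.076 at 25, but counts mostly the peaks its factor came from, so neither decides. The third, written before its value was seen, set the pileup ratio at strong shared regions away from gene ends against that near them and gave 0.961 (0.946 to 0.976), an interval that crosses the bound of 0.95, and with 1 library per genotype, loss of Dnmt3a and a library difference cannot be told apart.

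The strongest wild-type-only region lay inside Dnmt3a. Swapped labels stay open: the difference at the region (knockout minus wild-type peaks, -1) is fixed by its choice as a wild-type-only region, and the labels do not state which part of the gene the allele removes. Counting noise stays open too: 8 of the 3102 other wild-type peaks with a −log10 q of at least 15 had no knockout partner (0.258%, interval 0.111 to 0.508), and this region was picked for lacking one. Removal of the DNA by the engineered allele and loss of accessibility at intact DNA cannot be told apart, because 0 knockout peaks beyond the last shared region of the gene would follow from both.

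Chromosome 19 had the highest knockout-only share, 70.2% (interval 65.2 to 74.9). A deviation as large on any of 20 chromosomes appeared in 2.72% of 100000 random reassignments. These too treated unshared regions as independent, so the 2.72% may be too low and does not exclude chance. An extra copy of chromosome 19 in all knockout cells was argued against by the pileup ratio at shared regions, 1.007 times (0.978 to 1.04) that of the other chromosomes, where about 1.5 would be needed. A copy in a minority of the cells would give a smaller ratio and is not excluded. A difference tied to the genotype was not tested beyond this, and with 1 library per genotype a candidate explanation in either library stays open.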
